A study of Homo sapiens with 6 samples.

How the data were processed

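Total RNA from A2780 cells, collected 96 hours after lentiviral infection, was amplified, converted to labelled cDNA and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The virus medium was replaced at 24 hours, and cells grew in medium with 10% fetal bovine serum. The authors deposited 1 table of 33252 probe sets by 6 arrays, whose values are on a log2 scale as judged from their range. Per the submitters' processing notes, the deposited log2 values involved RMA, a method of background correction, normalization and probe summary. Its version, the software, and whether all arrays were normalized together are not given in the sources used here. The columns do not share the same quantiles. No value was missing, and any 2 arrays had at most 2 identical values.

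Probe sets were named from a platform annotation. Of 33252, 19460 had 1 gene symbol, 1754 had several and 12038 were not listed there. Several probe sets of a gene, as for 769 genes, were represented by the brightest on average. Probe sets with several symbols were left out, except the one for BMI1 and COMMD3-BMI1, which reads the target. This left 18418 genes. Gene order for the neighbourhood lists and gene spans for the receptor test came from RefSeq on GRCh38.p14. The array's build is not given in the sources used here, so no coordinates are printed.

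Groups followed the labels: 1 control and 2 hairpins for each of 2 targets. All 6 arrays entered 1 fit with 4 group means in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjustment over all genes at 0.05. Contrasts were each knockdown against its own control, their average and their difference. An exact permutation of 1 against 2 arrays cannot give a p under 0.333, so none was used. The 23 gene lists were fixed before the data were examined, and were tested with camera at a preset correlation of 0.01, adjusted over 92 tests together. The estimated correlation, fry, and 10000 random lists matched on expression were alternatives. Changes at 1.5-fold with both hairpins were counted without a test, beside 100 simulated sets of unchanged arrays. The simulated spread was taken from the fit, so it includes any real difference between the hairpins of a target. Lists shared few genes, at most 6 between apoptosis regulators and p53 targets. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

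Named genes followed a rule fixed at the same time. For each target it takes up to 12 genes per direction past the threshold, filled up to 8 by the smaller of the hairpin changes where too few pass, and up to 6 for the average and the difference. It adds up to 4 members with the smallest p of each list called, and always BMI1, FALEC, CDKN1A, MDM2, CDKN2A and CDKN2B. Because no gene passed, all named genes come from the filled part, the lists or the fixed names. FAS and the other genes named as shared between targets, and those named for the control arrays, were chosen after their values were seen.

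The fit was tested on simulated data for the BMI1 comparison, with 18418 genes and 20 runs. Of genes changed 2-fold, 0.15% were called, and of genes changed 4-fold, 33.4%, with a mean of 2.25 false calls. A list of 65 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 20 of 20 runs, both with the preset and with the estimated correlation, and an unchanged list in 0. Simulated genes varied independently of each other, so these runs do not measure the power for correlated lists.

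Alternatives fixed beforehand were pooled controls, the other target's control, filters on dim genes, quantile normalization, cyclic loess, the mean of probe sets, a variance trend, a robust prior, the hairpin number as a block, leaving out each knockdown array, and other thresholds. Gene lists under the other target's control, quantile normalization and cyclic loess were added after the data were seen.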

Results

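Gene expression was measured on 6 arrays of A2780, a human ovarian cancer cell line. Cells were infected with lentivirus carrying short hairpin RNAs (shRNAs), which lower a chosen transcript. The targets were BMI1, a subunit of Polycomb repressive complex 1, and FAL-1, a long non-coding RNA. Each target had 2 hairpins, with 1 array each, and 1 control array of its own. RNA was taken 96 hours after infection. The array values are log2 probe set summaries, with a median between 6.94 and 7.09 on each array. Arrays of the same target correlated at 0.985 to 0.995 across probe sets, and arrays of different targets at 0.973 to 0.987. The spread came only from the 2 hairpin pairs, with 2 residual degrees of freedom, and each lone control was assumed to vary like the hairpins. Separate cultures are not described, so limma's p-values for single genes measure only the spread between these samples. That spread may be technical, or it may come from differences between the hairpins, such as unequal knockdown. The number of arrays limits the precision.

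The targeted genes came first. The probe set that reads BMI1 is also annotated to the readthrough transcript COMMD3-BMI1, and it stood at 10.64 in the BMI1 control. It read 8.73 with BMI1 hairpin 1, which is 26.8% of the control level, and 9.99 with BMI1 hairpin 2, which is 64.0%. With the FAL-1 hairpins it read 10.84 and 10.51 beside 10.84 in their control, or 99.9% and 79.8%. The mean BMI1 change was -1.27 ± 0.89 (SD, n = 2 hairpins) and did not pass limma's test (adjusted p = 0.9998). FAL-1 (symbol FALEC) is not among the symbols annotated to the probe sets used here, so its knockdown was not checked. The lists of genes near each target moved by little. The 9 measured genes around BMI1 had a median log2 change of 0.05 with BMI1 knockdown, and the 27 around FALEC had 0.01 with FAL-1 knockdown. Neither list passed limma's camera test, which compares a list with all other genes (adjusted p = 0.503 and 0.666).

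**Figure D1:**
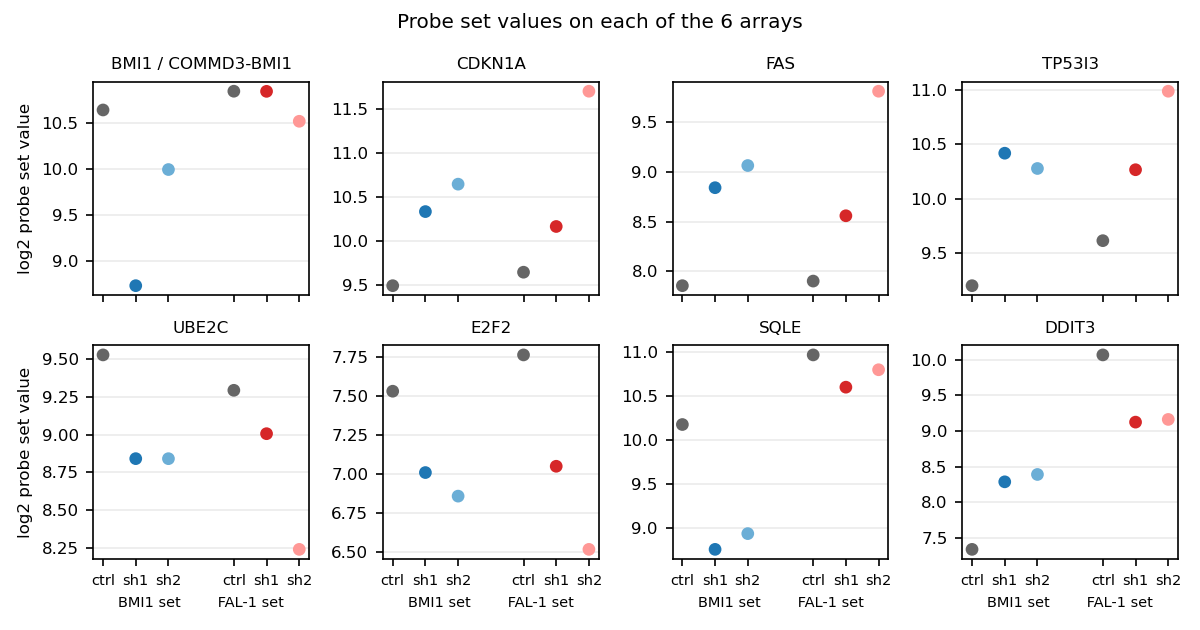
Log2 probe set values (vertical axes, each with its own range) on the control (ctrl) and the hairpin arrays (sh1, sh2) of the BMI1 and FAL-1 sets, 1 point per array, for 8 genes. BMI1 reads 10.64 in its own control and 8.73 and 9.99 with its hairpins, CDKN1A and FAS stand above the control with all 4 hairpins, and DDIT3 is 7.34 in one control and 10.07 in the other.

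With BMI1 knockdown, target genes of the tumour suppressor p53 rose and genes of the cell division cycle fell. The p53 target list had a median log2 change of 0.37 over 64 genes (adjusted p = 1.3e-14, camera), and 53 of the 64 were above the control with both hairpins. The list of G1/S and DNA replication genes fell, with a median of -0.56 (adjusted p = 1.0e-12) and 64 of 64 genes below the control with both hairpins. The list of G2/M and mitosis genes fell by 0.57 (adjusted p = 3.3e-09, camera), with 64 of 65 below. Of all genes tested, 32.9% were above the control and 30.7% below it with both BMI1 hairpins. The calls of these 3 lists rest on a preset correlation between genes. At that setting camera weighs the gene statistics of a list against their spread between genes, not between arrays. No list call in any comparison held with an estimated correlation (adjusted p = 0.912 for each of these lists). None held with fry, a rotation test of the list alone. With an estimated correlation, camera also uses only the 2 residual degrees of freedom of the fit. The hypoxia and glycolysis list with BMI1 knockdown had an estimated correlation of 0.0057, under the preset 0.01. Its unadjusted camera p still went from 2.1e-12 to 0.018. For that list the lost call therefore does not show that correlation between genes produced it. The other 3 lists had estimated correlations far over the preset: 0.467 for p53 targets, 0.825 for replication and 0.963 for mitosis. For these 3, the camera p at the preset may be far too small. No member of the 3 lists passed over all genes or adjusted over the list alone.

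Members of the p53 list with the smallest p included SESN2, a stress-induced regulator of growth signalling, at 1.01 ± 0.13 (SD, n = 2 hairpins). GDF15, a secreted stress factor, stood at 1.47 ± 0.01, ANKRA2 at 1.18 ± 0.04 and CYFIP2 at 0.73 ± 0.16. Several of these values depended on the control array. Against the FAL-1 control SESN2 read -0.43, GDF15 0.20 and ANKRA2 0.45, while CYFIP2 read 0.75. CDKN1A, which encodes the cell cycle inhibitor p21, was higher by 0.84 and 1.15. It was a gene of interest to the study, so it is not independent evidence. MDM2, the ubiquitin ligase that limits p53, read 0.24 and 0.23, and 0.41 on average against the FAL-1 control. CDKN2A and CDKN2B, inhibitor genes that Polycomb complexes can silence, read 0.19 ± 0.10 and 0.28 ± 0.15. Among replication genes E2F2 stood at -0.60 ± 0.11, SLBP at -0.32 ± 0.05, POLD1 at -0.70 ± 0.14 and UHRF1 at -0.92 ± 0.04, although a second UHRF1 probe set did not show this. Among mitosis genes UBE2C stood at -0.69 and CDC20 at -0.56 ± 0.07. Against the FAL-1 control CDKN2A read 0.08, SLBP -0.16, UBE2C -0.45 and CDC20 -0.29. The hairpin with the lower BMI1 level had the smaller medians for all 3 lists: 0.29 against 0.43 for p53 targets, -0.40 against -0.61 for replication and -0.33 against -0.74 for mitosis.

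With BMI1 knockdown the sterol synthesis list fell, with a median of -0.42 over 26 genes (adjusted p = 2.7e-12, camera) and 23 below the control with both hairpins. The median was -0.59 with hairpin 1, -0.26 with hairpin 2 and -0.88 against the FAL-1 control. Its members included SQLE, squalene epoxidase, at -1.33 ± 0.13, ACAT2 at -1.06 ± 0.42, EBP at -0.62 ± 0.05, and SREBF2, a transcription factor of sterol synthesis genes, at -0.62 ± 0.08. Against the FAL-1 control SQLE read -2.12 and SREBF2 -1.02. The hypoxia and glycolysis list fell by 0.31 over 33 genes (adjusted p = 2.0e-11), with 25 below with both hairpins. ENO2, a neuronal enolase, read -1.05 ± 0.06, HK2, a hexokinase, -0.91 ± 0.05, PFKP, a phosphofructokinase, -0.81 ± 0.08, and SLC2A1, a glucose transporter, -0.76 ± 0.14. Against the FAL-1 control PFKP read -0.48 and SLC2A1 -0.49. Adjusted over the list alone, 1 sterol gene and 2 hypoxia genes passed. The replication-dependent histone list fell (median -0.29, adjusted p = 0.0011), although H2BC11 and H4C8 were higher by 0.72 and 0.79. Against the FAL-1 control the median was -0.50, and these 2 genes read 0.01 and 0.03. With BMI1 hairpin 1 alone the histone call was lost (median -0.16, adjusted p = 0.308). With an estimated correlation the adjusted p = 0.912 for these lists.

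Smaller shifts were seen in other lists. NF-kappaB and immediate early genes rose (median 0.17, adjusted p = 0.019, camera), with FOS at 1.11 ± 0.09 and EGR1 at 0.90 ± 0.11, but the call was lost with BMI1 hairpin 1 alone (median 0.06, adjusted p = 0.676), and the median was -0.09 against the FAL-1 control (adjusted p = 0.367), where FOS read 0.05 and EGR1 -0.21. Oxidative phosphorylation genes fell (median -0.10, adjusted p = 0.037), a call lost with BMI1 hairpin 1 alone (adjusted p = 0.899) and after quantile normalization or cyclic loess (adjusted p = 0.127 and 0.187). Its median was -0.20 against the FAL-1 control. Its member COX7C was higher, at 0.85 ± 0.05. The adjusted p = 0.912 for the first list and 0.914 for the second with an estimated correlation. The unfolded protein and amino acid response list did not pass (median -0.17, adjusted p = 0.077, and a median of -0.69 against the FAL-1 control), with 1 member past the threshold adjusted over the list alone. The heat shock list did not pass either (adjusted p = 0.331), and its median of -0.10 and mean of 0.07 differ in sign. It too had 1 member adjusted over the list alone.

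No single gene passed limma's test for BMI1 knockdown among 18418 genes, and 477 had an unadjusted p under 0.05, of which 189 were higher and 288 lower. The genes named next were taken by the size of the smaller hairpin change and did not pass (adjusted p = 0.9998). HMOX1, heme oxygenase 1, was 5.40-fold higher, at a log2 change of 2.43 ± 0.10 (SD, n = 2 hairpins). DNAI3 read 1.49 ± 0.13, ANKRD20A8P 1.35 ± 0.05, HBP1, a transcriptional repressor, 1.26 ± 0.01, DENND2C 1.23 ± 0.01 and TULP3, a protein of primary cilia, 1.17 ± 0.03. The 6 probe sets of ANKRD20A8P were all higher, by 0.19 to 1.35, and the value given is the largest. Against the FAL-1 control HBP1 read 0.53 and DENND2C 0.57. PYGM, muscle glycogen phosphorylase, was 4.61-fold lower, at -2.21 ± 0.07. CKB, a creatine kinase, read -1.40 ± 0.09, IDO1, a tryptophan-degrading enzyme, -1.39 ± 0.29, CCNC, cyclin C, -1.21 ± 0.08, ATP1B2 -1.19 ± 0.06, TMEM145 -1.29 ± 0.20 and OSGEPL1 -1.16 ± 0.02. Both hairpins differed from the control by 1.5-fold or more the same way for 265 genes, 99 higher and 166 lower. Simulated unchanged arrays, whose hairpins also share 1 control, gave a mean of 229 and at most 263 in 100 sets. The simulated spread includes any real difference between hairpins, so these counts do not decide how many changes came from the knockdown.

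With FAL-1 knockdown the same 3 lists stood out. G1/S and DNA replication genes fell (median -0.56, adjusted p = 1.7e-14, camera), p53 targets rose (0.46, adjusted p = 3.2e-14), and G2/M and mitosis genes fell (-0.65, adjusted p = 1.0e-12). Adjusted p = 0.912 for each with an estimated correlation. No member passed over all genes or adjusted over the list alone. Both hairpins were above the control for 50 of 64 p53 targets, and below it for 46 of 64 replication genes and 33 of 65 mitosis genes. Of all genes tested, 37.2% were above and 27.7% below with both FAL-1 hairpins. Hairpin 2 carried most of the cell cycle shift. Its medians were -1.08 for replication and -1.37 for mitosis, beside -0.08 and -0.02 with hairpin 1. Without hairpin 2 the mitosis list did not pass (adjusted p = 0.935). The p53 targets were above the control with each, at 0.29 and 0.63.

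**Figure D2:**
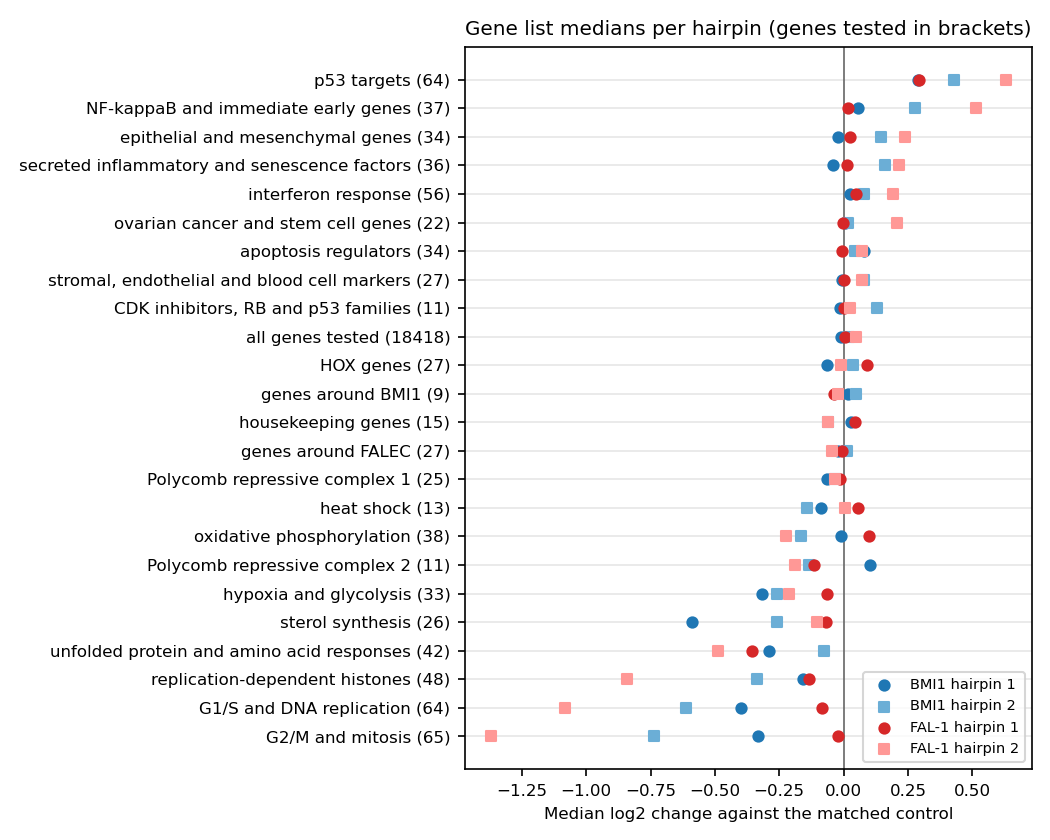
Median log2 change against the matched control (horizontal axis) of each gene list and of all genes tested, with 1 point per hairpin and the number of genes in brackets. The p53 targets lie between 0.29 and 0.63 with all 4 hairpins, and the mitosis list reaches -1.37 with FAL-1 hairpin 2 but -0.02 with FAL-1 hairpin 1.

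Among p53 targets, CDKN1A was higher by 0.52 and 2.05 with the FAL-1 hairpins and MDM2 by 0.32 and 0.64, and MDM2 by 0.30 on average against the BMI1 control. RRM2B, a ribonucleotide reductase subunit, read 0.73 ± 0.17 (SD, n = 2 hairpins), CYFIP2 0.70 ± 0.10, ZMAT3 1.24 ± 0.52 and FBXW7, a ubiquitin ligase subunit, 1.02 ± 0.42. CDKN2A read -0.07 ± 0.04 and CDKN2B 0.39 ± 0.47. E2F2 stood at -0.98 ± 0.38, WDHD1 at -1.03 ± 0.57, HELLS at -1.08 ± 0.52, E2F1 at -0.47 ± 0.34, KIF14 at -1.04 ± 0.83 and NUSAP1 at -0.96 ± 0.74. Against the BMI1 control CDKN2A read 0.05, HELLS -1.87 and E2F1 -0.23. Replication-dependent histones fell (median -0.49, adjusted p = 8.7e-09, camera), with H2AC15 at -1.32 ± 0.82, while H2BC11 and H4C8 were higher by 0.79 and 0.89, and by 1.49 and 1.65 against the BMI1 control. The histone median was -0.13 with hairpin 1 alone, and -0.14 against the BMI1 control, where the call was lost (adjusted p = 0.097). The hypoxia and glycolysis list fell (-0.13, adjusted p = 0.019), with ENO2 at -0.83 ± 0.10 and PFKP at -0.41 ± 0.03, while KDM3A and PFKFB3 were higher by 0.58 and 0.53. Against the BMI1 control PFKP read -0.74 and PFKFB3 0.22, and the list median was -0.04. That call was lost with hairpin 1 alone (adjusted p = 0.159), against the BMI1 control (0.070), and after quantile normalization (0.074) or cyclic loess (0.091). With an estimated correlation the adjusted p = 0.912 for both lists.

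The unfolded protein and amino acid response list fell with FAL-1 knockdown by 0.55 over 42 genes (adjusted p = 3.0e-11, camera, and adjusted p = 0.912 with an estimated correlation), and 4 genes passed adjusted over the list alone. DDIT3, a stress transcription factor also called CHOP, read -0.92 ± 0.03 (SD, n = 2 hairpins), DDIT4 -1.47 ± 0.33, VLDLR -0.95 ± 0.07 and STC2 -1.96 ± 0.03. The direction depended on the control array, because the FAL-1 control had high values of these genes. Against the BMI1 control the median was 0.04 (adjusted p = 0.658), DDIT3 read 1.80, DDIT4 -0.19, VLDLR -0.26 and STC2 -0.38.

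A further 4 lists rose with FAL-1 knockdown. NF-kappaB and immediate early genes had a median of 0.27 (adjusted p = 0.0063, camera), with NR4A2 at 0.65 and 2.35 with the hairpins, DUSP5 at 0.77 ± 0.58 and ATF3 at -0.74 ± 0.35, which turned to 0.33 against the BMI1 control, where NR4A2 read 2.62 and the list median was 0.52. Secreted inflammatory and senescence factors had 0.12 (adjusted p = 0.0086), with the collagenase gene MMP1 at 1.10 ± 0.30 and MMP3 at 1.18 ± 0.29, and MMP1 at 2.17 against the BMI1 control. The interferon response had 0.11 (adjusted p = 0.0086), with B2M at 0.42 ± 0.01 and IRF9 at 0.50 ± 0.17. Epithelial and mesenchymal genes had 0.13 (adjusted p = 0.014), with ITGA5 at 0.63 ± 0.19, TAGLN at 0.79 ± 0.49 and CLDN7 at -0.43 ± 0.10. Both kinds of genes are in that 1 list, so its median does not show a shift toward either kind. All of these calls were lost with hairpin 1 alone (adjusted p = 0.892, 0.615, 0.118 and 0.527), and with an estimated correlation (adjusted p = 0.912 for each). The epithelial and mesenchymal list also lost its call against the BMI1 control (adjusted p = 0.138), although its median there was 0.16. ACTA2 read -0.24 there instead of 0.94, and TAGLN 0.37. None had a member past the threshold adjusted over the list alone.

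No single gene passed limma's test for FAL-1 knockdown, and 563 of 18418 had an unadjusted p under 0.05, 286 higher and 277 lower. By the same rule as before, and without passing (adjusted p = 0.999), the genes with the largest values in both hairpins were NTS, neurotensin, at 1.78 ± 0.09 (SD, n = 2 hairpins), SMPD1 at 1.47 ± 0.38, ANXA1, annexin A1, at 2.07 ± 1.31, TULP3 at 1.19 ± 0.08, COL5A2 at 1.16 ± 0.10, EBI3 at 1.03 ± 0.03, RFPL4B at 1.44 ± 0.63 and TRIM55 at 1.28 ± 0.42. On the lower side were SLC7A11, a cystine transporter, at -2.53 ± 0.64, CHAC1 at -2.01 ± 0.05, PYGM at -1.61 ± 0.32, TUBE1 at -1.48 ± 0.20, RAB39A at -1.41 ± 0.25 and NUPR1 at -1.23 ± 0.09. Some of these values depended on the control array. Against the BMI1 control TRIM55 read 2.18, SLC7A11 read 0.10, CHAC1 -0.05, TUBE1 -0.38 and NUPR1 -0.18, while PYGM read -1.91 and RAB39A -1.72. Both hairpins differed by 1.5-fold or more for 223 genes, 106 higher and 117 lower. Simulated unchanged arrays gave a mean of 228 and at most 264, with the same limit of the simulated spread. Hairpin 2 stood apart from the other arrays, with 2064 genes at 1.5-fold or more against 463 for hairpin 1.

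The changes with both knockdowns resembled each other. Across genes, the mean BMI1 and FAL-1 changes correlated at a Pearson r of 0.562 and a Spearman rho of 0.467. Genes are not independent replicates, so no p is given. These changes share no control array, and simulated unchanged arrays gave an r near 0. Simulated genes varied independently, so that value was set by construction. It does not show what r genes that vary together would give without a knockdown effect. The covariance was 0.0364. Single hairpins of one target against single hairpins of the other gave 0.238 to 0.583, highest for the pair of hairpins 2. Hairpins of one target, which do share a control, correlated at 0.429 for BMI1 and 0.440 for FAL-1, where unchanged arrays gave 0.501 for both. Their covariances were 0.0342 and 0.0397 beside simulated values of 0.0362 and 0.0361. The simulated spread includes any real difference between hairpins, so the simulated values may overstate what a shared control adds. With each hairpin of a target set against a different control, the correlations were 0.243 for BMI1 and 0.343 for FAL-1. The covariances were then 0.0224 and 0.0354, so a shared control does not account for all of the covariance. These correlations lie within the range between targets. They are not like for like, because 1 hairpin was set against the other target's control. The difference between the control arrays thus enters them.

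Of the genes at 1.5-fold or more with both hairpins, 28 were higher with both targets and 16 lower, where independent lists would share 0.57 and 1.05. The higher genes included the p53 targets FAS, a death receptor, TP53I3 and ZMAT3, with mean log2 changes over both targets of 1.08 for TP53I3, and also TULP3 at 1.18, TRIM55 at 1.26, ACER2 at 1.30, ATP10D at 0.96 and HBP1 at 1.07. FAS was higher by 0.98, 1.20, 0.65 and 1.90 with the 4 hairpins. The lower genes included PYGM at -1.91, SEPTIN3 at -1.28, RAB39A at -1.20, ENO2 at -0.94, LTBP1 at -0.86 and FABP3, a fatty acid binding protein, at -0.81. DDIT3 was the single gene higher with BMI1 and lower with FAL-1, and 0 genes went the other way, where independent lists would share 0.63 and 0.96.

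**Figure D3:**
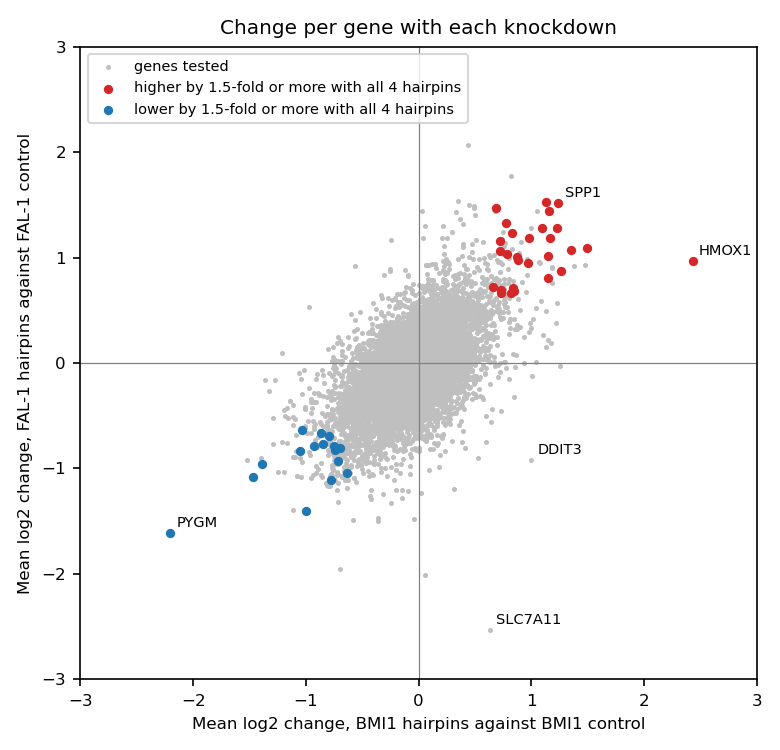
Mean log2 change of each gene tested with BMI1 knockdown (horizontal axis) and with FAL-1 knockdown (vertical axis), each over 2 hairpins against its own control. Red and blue points mark the 28 genes higher and the 16 genes lower by 1.5-fold or more with all 4 hairpins, and DDIT3 and SLC7A11 lie apart, with a positive mean for BMI1 and a negative mean for FAL-1.

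For the change averaged over both targets, 0 genes passed limma's test and 962 had an unadjusted p under 0.05 (433 higher and 529 lower). G1/S and DNA replication (median -0.59, adjusted p = 1.9e-17, camera), G2/M and mitosis (-0.62, adjusted p = 1.7e-14), histones (-0.38), hypoxia and glycolysis (-0.21), sterol synthesis (-0.24) and unfolded protein responses (-0.30) fell. The p53 targets (0.42, adjusted p = 2.2e-17), NF-kappaB and immediate early genes (0.27), secreted factors (0.07) and epithelial and mesenchymal genes (0.10) rose. Without BMI1 hairpin 2 the calls of NF-kappaB, secreted factors and epithelial and mesenchymal genes were lost (adjusted p = 0.055, 0.190 and 0.308), and without FAL-1 hairpin 2 those of the last 2 were lost (adjusted p = 0.314 and 0.088). Without FAL-1 hairpin 2 the medians were -0.32 for replication, -0.28 for mitosis, -0.21 for histones and 0.08 for NF-kappaB. With an estimated correlation the adjusted p = 0.912 for each of these lists. For p53 targets, 45 of 64 genes lay above the control with all 4 hairpins, which is 70.3% beside 17% of all genes tested. Adjusted over the list alone, 2 hypoxia genes, 1 sterol gene, 1 oxidative phosphorylation gene and 1 heat shock gene passed.

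The difference between the knockdowns was tested as an interaction. Of single genes, 0 passed limma's test and 148 had an unadjusted p under 0.05, with 86 higher and 62 lower. Sterol synthesis was lower with BMI1 than with FAL-1 knockdown (median difference -0.33, adjusted p = 8.4e-08, camera), as was hypoxia and glycolysis (-0.25, adjusted p = 1.2e-05). SQLE differed by -1.06, SREBF2 by -0.78, SLC2A1 by -0.81 and CCNC by -1.31. The unfolded protein and amino acid response list was higher with BMI1 than with FAL-1 knockdown (0.28, adjusted p = 6.8e-08), as were histones (0.13, adjusted p = 0.016), with DDIT3 differing by 1.92, CHAC1 by 2.07 and TUBE1 by 1.44. With both controls pooled, the unfolded protein and histone differences turned to -0.20 and -0.13, and those of DDIT3, CHAC1 and TUBE1 to -0.80, 0.11 and 0.33. The sterol difference was then -0.67 and that of SQLE -1.86. Pooled controls cancel out of the difference, so these values also hold any difference between the sets of arrays. The sterol list, for example, was 0.42 higher in the FAL-1 control than in the BMI1 control. Without FAL-1 hairpin 1 the sterol, hypoxia and unfolded protein differences were -0.21, -0.10 and 0.45, and without hairpin 2 the last was 0.14. Without FAL-1 hairpin 2 the histone difference was -0.14 (adjusted p = 0.088), and without BMI1 hairpin 1 it was 0.02 (adjusted p = 0.570). With an estimated correlation the adjusted p = 0.912 for all 4 lists. Neither the p53 targets (adjusted p = 0.619) nor the replication (0.393) and mitosis lists (0.201) passed.

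The remaining lists passed in none of the 4 comparisons. They were apoptosis regulators, CDK inhibitors with the RB and p53 families, genes around each target, heat shock, housekeeping genes, HOX genes, ovarian cancer and stem cell genes, Polycomb repressive complexes 1 and 2, and markers of stromal, endothelial and blood cells. HOX genes, which Polycomb complexes can silence, had medians of -0.01 with BMI1 and 0.03 with FAL-1 knockdown over 27 genes (adjusted p = 0.842 and 0.447, camera). Medians with BMI1 and FAL-1 knockdown were -0.06 and -0.04 for complex 1 (adjusted p = 0.595 and 0.448) and -0.08 and -0.14 for complex 2 (adjusted p = 0.666 and 0.218). They were 0.08 and 0.02 for the CDK inhibitors (adjusted p = 0.550 and 0.855), 0.02 and 0.04 for apoptosis regulators (adjusted p = 0.399 and 0.365), and 0.03 and 0.11 for ovarian cancer and stem cell genes (adjusted p = 0.976 and 0.156). Heat shock genes had 0.05 with FAL-1 knockdown (adjusted p = 0.363), housekeeping genes -0.06 and -0.01 (adjusted p = 0.494 and 0.706), and the other cell type markers 0.04 and 0.06 (adjusted p = 0.770 and 0.461). Of lists called elsewhere, sterol synthesis did not pass with FAL-1 knockdown (-0.08, adjusted p = 0.233, and a median of 0.35 against the BMI1 control), nor did oxidative phosphorylation (-0.06, adjusted p = 0.454). Secreted factors (0.06, adjusted p = 0.269), the interferon response (0.07, adjusted p = 0.491) and epithelial and mesenchymal genes (0.08, adjusted p = 0.450) did not pass with BMI1 knockdown.

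The control arrays themselves differed. By log2 value, 303 genes were at least 1.5-fold higher and 166 at least 1.5-fold lower in the FAL-1 control than in the BMI1 control. DDIT3 read 7.34 in the BMI1 control and 10.07 in the FAL-1 control, and SLC7A11 read 6.898 and 9.53. The sterol synthesis list was 0.42 higher and the unfolded protein list 0.48 higher in the FAL-1 control, while the p53 targets differed by 0.05, replication genes by -0.08 and mitosis genes by -0.15. With 1 array each, this difference was not tested.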

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

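The test that sets the FAL-1 knockdown against the BMI1 control was chosen only after its result was seen. The renormalization test was added after the data were seen, but before its own result.

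The difference between knockdowns passed camera for 4 lists, none of them with an estimated correlation. The unfolded protein and amino acid response list differed by 0.28 (BMI1 change minus FAL-1 change, median log2), sterol synthesis by -0.33, hypoxia and glycolysis by -0.25 and replication-dependent histones by 0.13.

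The fall of the unfolded protein and amino acid response list with FAL-1 knockdown kept at least 0.964 of its size after quantile normalization or cyclic loess. This argues against remaining differences in scaling between the arrays as its cause. The normalization by the authors was not undone, so it was not tested. Against the BMI1 control the list median was 0.04, within the range of random lists (-0.08 to 0.13). The FAL-1 control had the highest level of the 6 arrays (0.50 above the gene means, with 0.14 for the next). A candidate explanation is therefore a high FAL-1 control array, for example from the state of that culture. An effect of FAL-1 on these genes stays open as well, since the FAL-1 hairpins are compared with the control that was made with them, and a second FAL-1 control array was not analysed here.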

How the results depend on the processing

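The gene lists under the other target's control, quantile normalization and cyclic loess were chosen after seeing the data. The number of arrays limits all of these results. Under every alternative run, 0 genes passed for each of the 4 comparisons. With the replicate block of hairpin number the count was also 0 for each, while genes at an unadjusted p under 0.05 went from 477 to 782 for BMI1, 563 to 1064 for FAL-1, 962 to 1554 for the average and 148 to 286 for the difference. The labels link a BMI1 hairpin to a FAL-1 hairpin only by its number. The difference between hairpins 1 and 2 correlated at 0.275 across genes between the targets. Whether arrays of the same number were handled together is not given in the sources used here. With pooled controls the smallest adjusted p in limma was 0.23, 0.44, 0.27 and 0.23. There 1195, 1762, 1249 and 2071 genes had an unadjusted p under 0.05. For the difference, pooled controls cancel out, so it also holds any difference between the sets of arrays.

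Genes at 1.5-fold with both hairpins numbered 265 for BMI1 and 223 for FAL-1. They numbered 36 and 18 at 2-fold, where simulated unchanged arrays gave means of 37.0 and 35.6. At the lowest threshold tried they numbered 1213 and 1160, where these gave 1106 and 1103. As above, the simulated spread includes any real difference between hairpins. They numbered 556 and 732 with the control of the other target. The correlation of the fold changes was 0.24 to 0.58 between single hairpins. With pooled controls it was 0.436, where unchanged arrays gave 0.4998, with a covariance of 0.0305 beside 0.0181.

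Of 92 list tests 32 were called, and 35 with pooled controls, 33 without the dimmer genes, 33 with the replicate block, 28 after quantile normalization, 28 after cyclic loess and 30 to 45 without 1 knockdown array. The count was 0 with an estimated correlation and 0 with fry, where the medians stay as they are by construction. For BMI1 these medians were 0.370 for p53 targets, -0.564 for G1/S, -0.417 for sterol synthesis, -0.310 for hypoxia, -0.570 for G2/M, -0.293 for histones, 0.173 for NF-kappaB and -0.0976 for oxidative phosphorylation. For FAL-1 they were -0.562 for G1/S, 0.462 for p53 targets, -0.645 for G2/M, -0.549 for the unfolded protein response, -0.488 for histones, 0.268 for NF-kappaB, 0.120 for secreted factors, 0.108 for interferon, 0.134 for epithelial and mesenchymal genes and -0.130 for hypoxia. For the difference they were 0.279 for the unfolded protein response, -0.330 for sterol synthesis, -0.246 for hypoxia and 0.134 for histones. The oxidative phosphorylation median lay at the 9.35th percentile of random lists.

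Further calls were lost, and the cause was not tested. With pooled controls NF-kappaB with BMI1 was 0.0177, and the differences turned to -0.200 for the unfolded protein response and -0.134 for histones. Without the dimmer genes oxidative phosphorylation was -0.130, FAL-1 hypoxia -0.126 and the histone difference 0.137. After quantile normalization and cyclic loess oxidative phosphorylation was -0.0879 and -0.0777, and FAL-1 hypoxia -0.121 and -0.125.

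Leaving out 1 array at a time, with the other target's control where the own control was left out, gave these ranges. For BMI1, sterol synthesis ran from -0.880 to -0.257, G2/M from -0.737 to -0.332, histones from -0.501 to -0.156, NF-kappaB from -0.0858 to 0.276 and oxidative phosphorylation from -0.204 to -0.0119. For FAL-1, G1/S ran from -1.08 to -0.0820, p53 targets from 0.294 to 0.632, G2/M from -1.37 to -0.0214, the unfolded protein response from -0.549 to 0.0414, histones from -0.841 to -0.135, NF-kappaB from 0.0174 to 0.520, secreted factors from 0.0119 to 0.215, interferon from 0.0485 to 0.192, epithelial and mesenchymal genes from 0.0248 to 0.239 and hypoxia from -0.211 to -0.0357. For the average, histones ran from -0.562 to -0.209, G1/S from -0.837 to -0.317, G2/M from -0.978 to -0.279, NF-kappaB from 0.0778 to 0.395, secreted factors from 0.0175 to 0.141 and epithelial and mesenchymal genes from 0.0388 to 0.147. Of the differences, histones ran from -0.144 to 0.497, sterol synthesis from -0.453 to -0.209, hypoxia from -0.311 to -0.0971 and the unfolded protein response from 0.137 to 0.452.

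Of single genes that did not pass, some turned in sign. With BMI1 knockdown EGR1 ran from -0.206 to 0.975 and SESN2 from -0.430 to 1.10. With FAL-1 knockdown SLC7A11 ran from -2.98 to 0.0959, ACTA2 from -0.244 to 1.33, ATF3 from -0.983 to 0.331, DDIT3 from -0.942 to 1.80, BMI1 from -0.325 to 0.0397 and CDKN2A from -0.0967 to 0.0458. With pooled controls DDIT3 was 0.440 with FAL-1 and -0.804 for the difference, and MGP was 0.379 for the difference.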

Other observations

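The test with exchanged controls was chosen only after its result was seen, as were the values of the taste receptor genes in PRH1 and the count of other receptor genes as high. The other tests were chosen before their own results were seen. The receptor test was corrected after a first result had been seen, because an alternate locus had been given a false host gene, and because only genes in expressed hosts had been compared where the written rule named all hosts. The correction changed both readings: before it, genomic DNA was left open and unspliced RNA was argued against.

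The rise of p53 targets with the fall of replication and mitosis genes, which with FAL-1 rests mostly on hairpin 2 (medians of -0.08 and -0.02 with hairpin 1), was set against technical explanations. With the other target's control, each of the 6 list medians kept at least 0.680 of its value, which argues against a single unusual control array. After quantile normalization or cyclic loess these medians kept at least 0.942, which argues against remaining differences in scaling between the arrays. Such differences were small beforehand, with a median change per hairpin of -0.008 to 0.048. The normalization by the authors was not undone, so it was not tested. Whether the knockdowns slow division, and whether through p53, was not tested and stays open. A response to hairpins or lentivirus that the controls did not carry to the same degree was not tested either. It may bear on the order of the BMI1 hairpins. The p53 median was 0.43 without hairpin 1 and 0.29 without hairpin 2. The hairpin that lowered BMI1 less thus had the larger median.

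Some genes without introns were brighter on the BMI1 set of arrays, among them GPR52, at 8.34 in the BMI1 control and 6.11 in the FAL-1 control, TAS2R14, at 8.59 and 6.69, and OR2J3, at 8.32 and 5.203. All 8 taste receptor genes placed within PRH1 were higher on the BMI1 set, by 1.29 to 2.12. Genomic DNA on that set would raise receptor genes everywhere, but 315 receptor genes that lie in no other protein-coding gene differed by a median of 0.016 (SD over genes 0.223), beside a range of 0.060 over the arrays, and only 2 of them, OR2J3 and OR2D2, were higher by as much as the PRH1 genes (3.09 and 1.43). The rule set beforehand, a value under 0.0174, taken from the median of nested receptor genes (0.0347), was met only narrowly, because 38 of the 46 nested receptor genes did not differ either (median 0.007), so the weight lies on the PRH1 genes. Unspliced RNA of a host gene may be the source for genes other than OR2J3 and OR2D2, but this cannot be told apart from other causes. Of the 365 olfactory and taste receptor genes tested, 0 lay in a host gene that was measured and expressed. Genes of other kinds, such as GPR52, were not placed in host genes, so they did not enter this test. No biological explanation was tested.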
